A study of Homo sapiens with 9 samples.

How the data were processed

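RNA-seq was analysed in 9 libraries of HEK293 cells, 3 of wild type, 3 of an empty vector line and 3 of an inducible B3GALT2 line, grouped by the genotype in the labels. Per the labels' protocols, 500000 cells were seeded per well, and poly(A) RNA was enriched with oligo(dT) beads, made into libraries with an NEBNext Ultra kit and sequenced on a NovaSeq instrument. The deposited count table holds whole-number read counts per gene for 43294 genes named by Entrez identifier and symbol, not normalized by the authors. The deposited TPM table holds TPM (transcript levels scaled for length and library size) computed by the authors, and how is not given in the sources used here. The submitters' processing notes name bcl2fastq 2.20, FastQC, STAR, featureCounts and the build hg38. Versions of the aligner and counter, the annotation, the use of strand and the treatment of multi-mapping reads are not given in the sources used here. Reads of overlapping, antisense and near-identical genes can therefore not be told apart. Identifiers were matched to an annotation of GRCh38.p14 for positions, 43152 of 43294, and the unmatched genes held 0.0087% of counts. No column was left unused.

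Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 (17080 genes, 99.908 to 99.946% of counts), libraries were scaled by TMM (factors 0.942 to 1.02), and all 9 libraries were fitted in one robust quasi-likelihood model without covariates. The common biological coefficient of variation was 0.0548. P-values were adjusted by Benjamini-Hochberg over all tested genes for each of 3 comparisons, with calls at 0.05, and a 2-fold call also needed an absolute log2 fold change of 1. Levels are TMM-scaled CPM. The tests are two-sided. Intervals for ratios of few reads cover counting error only and are exact 95% intervals. Those of medians over genes are 95% bootstrap intervals that resample genes and not libraries. Library totals ran from 20283707 to 39050475, so a gene at 1 CPM rests on few reads.

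Before the data were examined, 40 gene lists were fixed: glycosyltransferases and glycan supply, glycolipids, proteoglycans and lectins, ASO uptake, trafficking and RNase H, endocytosis, lysosome and Golgi, stress responses and chaperones, energy metabolism and lipids, interferon, NF-kappaB and p53, cell cycle and histones, ribosomal proteins, matrix, cadherins, immediate early genes, and markers of neuronal, kidney, hepatocyte, fibroblast, leukocyte and keratinocyte types. The 38 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on voom values, adjusted over lists within a comparison. Leukocyte markers (2 tested) and mitochondrially encoded genes (0 in the table) were not tested. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list moves one way and does not compare it with other genes.

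Genes were named by a rule fixed before the data were examined. B3GALT2 was always named. Genes qualified with an adjusted p under 0.05, CPM that did not overlap between groups, a mean of 5 CPM or more and a symbol that is not a locus, antisense or small RNA placeholder. Of these, the 10 largest rises and falls were named against empty vector, 6 and 6 in each other comparison, and 10 and 10 among genes changed the same way against both controls, ranked by the smaller change. For each list described, up to 2 rises and 2 falls at 1 CPM or more were named. MSR1, RNASEH1, M6PR, STAB1, STAB2, GCC2, ANXA2 and CDC73 were always given where measured. Overlapping partner genes, neighbours of MSR1, and members given to explain a count, were named after their values were seen. Some genes that the rule selected are not reported here.

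Alternatives fixed before the data were examined were RLE factors, library totals as the only scaling, DESeq2 1.42.0, no low-count filter, a filter at a mean of 5 CPM, fits of only the groups compared, replicate number as a block, limma on log2(TPM + 1), and each library left out. Chosen after seeing the data were protein-coding genes only, trends with length and GC removed per library (both known for 86.0% of tested genes), and a factor of the variation within groups as a covariate. For shared libraries, unchanged groups were simulated 20 times.

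The test was checked on simulated counts with 17080 genes per comparison. At 1.5-fold it recovered 85, 86 and 83% of 100 changed genes for B3GALT2 against empty vector, B3GALT2 against wild type and empty vector against wild type, and at 2-fold 98, 99 and 97%, with 14, 8 and 13 calls on unchanged genes. The changed genes had a mean of 1 CPM or more, and each gene had the same spread in all groups. Genes at lower levels, and the wider spread between wild type replicates, are therefore not covered. A list shifted 1.25-fold was called in each comparison and 0 of 37 others were. Genes were drawn independently there, so the check does not cover false calls of lists whose members vary together. In the data the estimated correlation was 0.917 for cytosolic ribosomal proteins in B3GALT2 against empty vector. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.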

Results

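Polyadenylated RNA was sequenced from HEK293 cells, a human embryonic kidney line, in 9 libraries. There were 3 libraries each from wild type cells, from cells carrying an empty inducible vector, and from cells carrying an inducible vector for B3GALT2. B3GALT2 encodes a Golgi enzyme that adds galactose in a beta1,3 linkage to N-acetylglucosamine on glycans. The series concerns an overexpression screen for the activity of antisense oligonucleotides (ASOs), short nucleic acids that bind a target RNA, and the stated question was how B3GALT2 overexpression changes gene expression. Cells were harvested 72 h after induction. The labels conflict on the doxycycline dose of the vector lines, which the protocol gives as 1000 ng/mL and the sample description as 0 ng/mL. Wild type cells were labelled untreated, so comparisons with them combine the vector with any doxycycline. Total counts were 26211833, 20283707 and 24484976 in wild type replicates 1 to 3, 28488206, 39050475 and 37375338 in empty vector, and 28422775, 35316451 and 28206666 in B3GALT2. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Throughout, a gene is followed by its log2 fold change from edgeR ± standard error. That error was derived as the absolute log2 fold change over the square root of edgeR's test statistic F. Levels are mean CPM (counts scaled to library size) ± SD, and n was 3 libraries per group. Genes said to rise or fall had an adjusted p under 0.05 over 17080 tested genes.

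B3GALT2 itself (gene 8707) was read 29559, 36316 and 31079 times in the B3GALT2 libraries, 3, 3 and 3 times in empty vector and 0, 1 and 3 times in wild type. Its level in the B3GALT2 line was 1044 ± 36.4 CPM. The ratio of its CPM to that in empty vector was 12292 (95% counting interval 6475 to 26883), and to that in wild type 18712 (7308 to 68677). Both rises passed the test, with adjusted p = 6.7e-18 and 1.4e-17 by edgeR's quasi-likelihood test. Empty vector and wild type did not differ detectably at these few reads (ratio 1.52, interval 0.425 to 6.76). The gene lies on chromosome 1 from 193178730 to 193186613 (GRCh38.p14 annotation), inside the span of CDC73, a transcription elongation factor gene, from 193122031 to 193254815. CDC73 had a log2 fold change of 0.09 ± 0.06 against empty vector, which did not pass (adjusted p = 0.24, edgeR). Gene counts do not separate transcripts of the vector from those of the native gene.

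MSR1 (gene 4481), a class A scavenger receptor that takes up polyanionic ligands, fell in the B3GALT2 line against both controls. Its level was 455 ± 28 CPM in B3GALT2, 1026 ± 30.0 in empty vector and 1539 ± 4.73 in wild type. The log2 fold change was -1.18 ± 0.05 against empty vector and -1.76 ± 0.05 against wild type, and empty vector was itself below wild type (-0.58 ± 0.05). MSR1 lies on chromosome 8 from 16107881 to 16192651 (GRCh38.p14). The titles of the samples carry the word Griptite (spelled Griptitite for wild type), which the labels do not explain, and gene counts do not separate MSR1 transcripts of a construct, if any, from native ones.

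**Figure D1:**
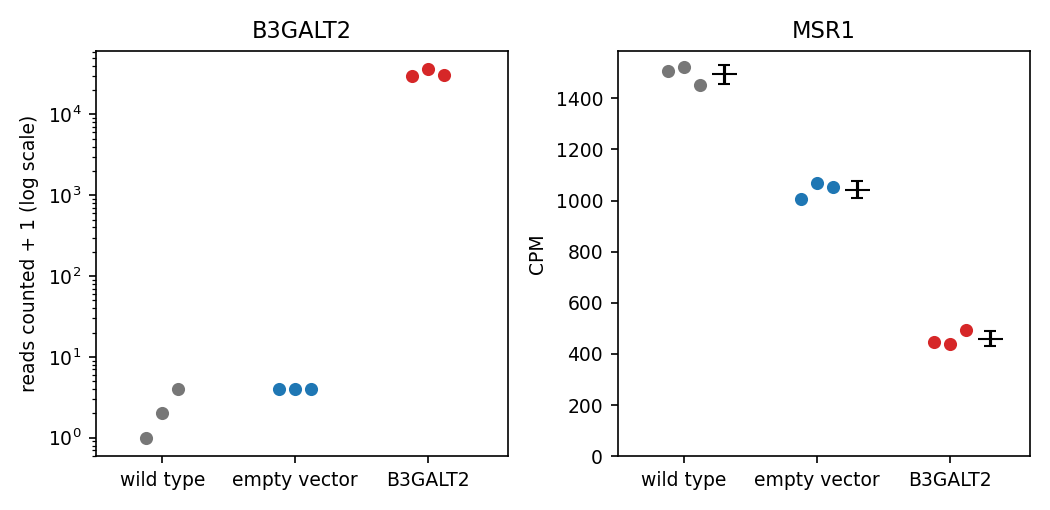
B3GALT2 reads per library (left, log axis of reads plus 1) and MSR1 CPM per library without scaling factors (right), by group, with points for the 3 libraries of each group and, for MSR1, bars for the mean and SD. B3GALT2 was read 29559 to 36316 times in its own line and 0 to 3 times in the controls, and MSR1 was lowest in the 3 B3GALT2 libraries (439.8 to 493.8 CPM).

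In a principal component analysis of the tested genes with a mean of 5 CPM or more, component 1 held 74.6% of the variance and component 2 held 16.4%. On component 1 the B3GALT2 libraries (-8.28 to -7.82) lay between empty vector (-22.76 to -18.90) and wild type (20.99 to 39.30). On component 2 they were apart from both. Wild type replicate 3 stood apart from its group, at 39.30 on component 1 against 25.96 and 20.99. Chi-square per gene between replicates was 16.5 and 21.9 for the pairs with that library and 3.06 for the other wild type pair, against 1.86 to 3.04 in the vector lines. No pair of libraries agreed within sampling noise.

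**Figure D2:**
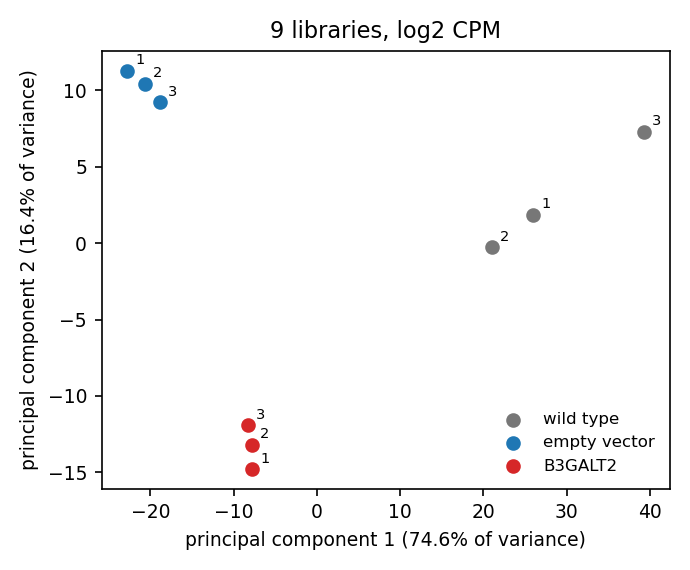
Principal components 1 and 2 of log2 CPM of the 9 libraries, over tested genes with a mean of 5 CPM or more. The share of variance is given on each axis and the group is shown by colour. Wild type replicate 3 is at 39.30 on component 1, and the B3GALT2 libraries lie between the controls on component 1 and below both on component 2.

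The comparison of B3GALT2 with empty vector is between lines that both carry a vector. With a single line of each kind, an effect of B3GALT2 cannot be told apart from other differences between the lines. Genes of the integrated stress response, which ATF4 switches on when amino acids are short or protein folding is disturbed, rose together. Of its 34 tested members 26 rose, 1 fell and 7 did not pass (27 and 1 adjusted over the list alone), with a median log2 fold change of 0.46. CHAC1, which degrades glutathione, rose most (1.90 ± 0.16), from 3.26 ± 0.714 to 12.2 ± 1.86 CPM. DDIT4, an inhibitor of mTORC1 (1.23 ± 0.11), and SLC7A11, the cystine transporter (0.67 ± 0.13), rose too. The single member that fell was ATF5 (-0.67 ± 0.09), which overlaps the more highly counted NUP62. The list was called by camera (adjusted p = 1.6e-15), and adjusted p was 0.261 with an estimated correlation.

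Rising lists also included the G2/M cell cycle, the mitotic genes, where of 35 members 15 rose, 0 fell and 20 did not pass (15 and 0 adjusted over the list alone), with NDC80 (0.37 ± 0.05) and NEK2 (0.33 ± 0.06) among them. Its call (adjusted p = 7.6e-06, camera) held with an estimated correlation (adjusted p = 0.0446), and no other list's call in this comparison did. Between B3GALT2 and wild type, however, 6 of these genes rose and 16 fell (adjusted p = 0.122, camera). In empty vector against wild type 4 rose and 21 fell, so the rise is relative to a low level in empty vector. Of 75 cytosolic ribosomal proteins 22 rose, 0 fell and 53 did not pass (25 and 0 adjusted over the list alone), with a median of 0.17 and RPL13A (0.32 ± 0.10) and RPL3 (0.30 ± 0.07) as examples (adjusted p = 5.0e-10, or adjusted p = 0.659 with an estimated correlation). Reads of these genes can also be shared with their many processed pseudogenes. Of 33 glycolysis and hypoxia genes 16 rose, 1 fell and 16 did not pass (18 and 2 adjusted over the list alone), with the mitophagy receptor BNIP3 (0.58 ± 0.10) and PDK1 (0.49 ± 0.10), which restrains pyruvate oxidation, rising and the glycolytic enzyme GPI (-0.15 ± 0.04) falling (adjusted p = 9.7e-05, or adjusted p = 0.583 with an estimated correlation).

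Cell surface and matrix lists rose as well. Of 21 proteoglycan core proteins 7 rose, 0 fell and 14 did not pass (7 and 0 adjusted over the list alone), among them CD44, a hyaluronan receptor (0.46 ± 0.07), and the heparan sulfate carrier GPC3 (0.44 ± 0.06) (adjusted p = 0.00261, or adjusted p = 0.201 with an estimated correlation). Between B3GALT2 and wild type 3 of the 21 proteoglycan genes rose and 11 fell (adjusted p = 0.136, camera), so the list was not raised against both controls. Of 39 extracellular matrix and adhesion genes 12 rose, 3 fell and 24 did not pass (12 and 3 adjusted over the list alone). TNC, which encodes tenascin C, rose (0.84 ± 0.11), as did the integrin gene ITGB3 (0.49 ± 0.14), while the collagen gene COL3A1 (-1.22 ± 0.20) and the fibrillin gene FBN2 (-0.36 ± 0.08) fell (adjusted p = 0.0198, or adjusted p = 0.397 with an estimated correlation). Of 26 neuronal genes that HEK293 cells are known to express 9 rose, 1 fell and 16 did not pass (9 and 1 adjusted over the list alone), with CRMP1 (1.21 ± 0.22), which overlaps the more highly counted EVC, and STMN3 (0.39 ± 0.08) rising (adjusted p = 0.00368, or adjusted p = 0.179 with an estimated correlation). Of 28 p53 targets 10 rose, 3 fell and 15 did not pass (11 and 4 adjusted over the list alone), with SESN2 (0.63 ± 0.07) and GADD45A (0.49 ± 0.06) rising and TP53I3 (-0.43 ± 0.10) and BAX (-0.25 ± 0.06) falling (adjusted p = 0.0469, or adjusted p = 0.397 with an estimated correlation).

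Lipid and chaperone lists fell. Of 25 cholesterol synthesis and uptake genes 1 rose, 10 fell and 14 did not pass (1 and 10 adjusted over the list alone), with ACAT2 (-0.46 ± 0.06), which overlaps the more highly counted TCP1, and lanosterol synthase LSS (-0.45 ± 0.05) falling and the sterol carrier STARD4 (0.31 ± 0.07) rising (adjusted p = 3.0e-04, or adjusted p = 0.439 with an estimated correlation). Of 17 fatty acid synthesis genes 1 rose, 7 fell and 9 did not pass (1 and 7 adjusted over the list alone), with FASN, the fatty acid synthase (-0.56 ± 0.05), and the elongase ELOVL6 (-0.28 ± 0.06) falling and the desaturase SCD5 (0.32 ± 0.06) rising (adjusted p = 0.0198, or adjusted p = 0.223 with an estimated correlation). Of 25 heat shock and chaperone genes 1 rose, 11 fell and 13 did not pass (1 and 11 adjusted over the list alone). The constitutive chaperone HSPA8 (-0.51 ± 0.06) and HSPA1A (-0.40 ± 0.06), which can share reads with its near-identical copy HSPA1B, fell, and the transcription factor HSF2 rose (0.23 ± 0.05) (adjusted p = 0.00150, or adjusted p = 0.286 with an estimated correlation).

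Among genes that qualified for naming (a mean of 5 CPM or more and groups that did not overlap), SORCS1, a sorting receptor (1.31 ± 0.10), ADM2, a peptide hormone (1.04 ± 0.12), PCK2, mitochondrial phosphoenolpyruvate carboxykinase (1.01 ± 0.10), HAPLN2 (0.95 ± 0.17), ZC3H6 (0.94 ± 0.11), JDP2 (0.89 ± 0.12) and SDHAF4 (0.88 ± 0.10) were the other large rises. The largest falls among the same genes were in LTB4R, a leukotriene B4 receptor (-1.44 ± 0.15), YJEFN3 (-1.40 ± 0.13), LY6G5B (-1.36 ± 0.11), KCNQ1OT1 (-1.30 ± 0.16), EME2 (-1.27 ± 0.11), ZDHHC11 (-1.26 ± 0.12), HOXD9 (-1.26 ± 0.11) and FAM95C (-1.21 ± 0.13), the hormone gene AMH (-1.18 ± 0.11) and MSR1. LY6G5B overlaps the more highly counted CSNK2B, and EME2 overlaps MRPS34, so their reads are uncertain. KCNQ1OT1 is antisense to KCNQ1, and no source used here states that counting used strand.

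Glycosylation lists were not called by camera. In the 11 members of the beta1,3-galactosyltransferase family 3 rose, 2 fell and 6 did not pass, and the family's mean (1.23, set by B3GALT2) and median (-0.006) differed in sign (adjusted p = 0.533). Beside B3GALT2, B3GALT1 rose (0.36 ± 0.11), and C1GALT1C1, the chaperone of core 1 O-glycan synthesis (-0.18 ± 0.06), and B3GALT6 (-0.18 ± 0.06) fell. Sialyl- and fucosyltransferases had 5 of 27 higher, among them the polysialyltransferase ST8SIA2 (0.63 ± 0.18), and 4 lower (adjusted p = 0.478). Glycosphingolipid synthesis had 4 of 24 higher and 0 lower (adjusted p = 0.0571, with 0 and 0 adjusted over the list alone), with the ceramide synthase CERS4 (0.34 ± 0.10) rising. GM3 synthase ST3GAL5 (0.23 ± 0.08) passed here by edgeR but not with library totals (adjusted p = 0.0735), DESeq2 (0.0567), a filter at a mean of 5 CPM (0.0729), limma on the TPM scale (0.280), protein-coding genes only (0.0632) or trends with length and GC removed (0.0568), nor in 6 of the runs that left out 1 library (up to 0.193). Such runs also ended the edgeR calls of B3GALT1 (3 runs, adjusted p up to 0.0987), C1GALT1C1 (6, 0.193), B3GALT6 (7, 0.204), CERS4 (3, 0.0972), ST8SIA2 (2, 0.0976) and MOGS (6, 0.194), and without a low-count filter those of C1GALT1C1 (0.109), B3GALT6 (0.0691) and MOGS (0.0595) ended. For N-glycan trimming and branching, where MGAT3 rose (0.43 ± 0.07) and MOGS fell (-0.18 ± 0.06), adjusted p was 0.533. It was 0.533 for the beta1,3-GlcNAc and beta1,4-galactosyltransferases, whose median (0.06) and mean (-0.06) differed in sign. For nucleotide sugar supply it was 0.174, for heparan and chondroitin sulfate synthesis 0.60 and for galectins and lectins 0.557. Fry, which does not compare a list with other genes, called the beta1,3-galactosyltransferase family, B3GALT2 included, higher (adjusted p = 2.61e-04). It also called higher glycosphingolipid synthesis (0.00354), sialyl- and fucosyltransferases (0.0121), nucleotide sugar supply (0.021) and beta1,3-GlcNAc and beta1,4-galactosyltransferases (0.0351). Galectins and lectins were called lower by fry (0.0345), and N-glycan trimming (0.115) and heparan and chondroitin sulfate synthesis (0.47) were not called.

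Lists for the uptake and action of ASOs were not called by camera either. Of 17 surface binding and uptake receptors 5 rose, 3 fell and 9 did not pass (5 and 3 adjusted over the list alone, adjusted p = 0.812). SCARA5, a ferritin scavenger receptor, rose (1.67 ± 0.19, mean level 2.71 CPM), and AGER fell (-0.70 ± 0.12) beside MSR1. Both had changed the opposite way between empty vector and wild type, where SCARA5 fell and AGER rose. The AGER call there ended with the covariate (0.754, adjusted p = 0.111, edgeR). Of 36 endosomal trafficking and release factors 3 rose, 6 fell and 27 did not pass (3 and 6 adjusted over the list alone, adjusted p = 0.627), with the endosomal GTPases RAB27A (0.27 ± 0.07) and RAB11A (0.24 ± 0.04) rising. Of 26 RNase H and ASO-binding nuclear proteins 0 rose, 7 fell and 19 did not pass (0 and 7 adjusted over the list alone, adjusted p = 0.0571). RNASEH1, the enzyme that cleaves RNA paired with DNA, had a log2 fold change of -0.05 ± 0.07, the mannose 6-phosphate receptor M6PR -0.15 ± 0.05, the trans-Golgi protein GCC2 0.07 ± 0.08 and ANXA2 -0.03 ± 0.06, none of which passed. STAB1 and STAB2, stabilin receptors, had 1 to 15 reads per library and were not tested. By fry the surface receptors, MSR1 included (adjusted p = 5.15e-04), and the RNase H and ASO-binding nuclear proteins (0.00684) were called lower. The trafficking factors were not called by fry (0.254).

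In all, 4762 genes changed by edgeR's quasi-likelihood test, 2183 higher and 2579 lower, and 582 changed at least 2-fold, 51 higher and 531 lower, of which 261 lower were lncRNAs. The 582 were 42 with a filter at a mean of 5 CPM, 106 on the TPM scale and 224 with protein-coding genes only. Of those 582 genes, 530 had changed the opposite way between empty vector and wild type. Both comparisons use the empty vector libraries, which favours opposite signs, and no count expected from that was computed for the 530. The 3 libraries of each group did not overlap in 53.7% of genes, where chance gives 10%. The count of 4762 was 3008 without empty vector replicate 1, 3162 without B3GALT2 replicate 1, 7560 without wild type replicate 3, 7888 with wild type left out of the fit and 7580 with a factor of the variation within groups as a covariate, and 31.7% of calls were higher on the TPM scale against 45.8% here. The call of fatty acid synthesis ended without empty vector replicate 3 (adjusted p = 0.0679), and that of p53 targets without B3GALT2 replicate 2 (0.0625), wild type replicate 1 (0.0533) or 3 (0.0554), or empty vector replicate 2 (0.0649), and with a filter at a mean of 5 CPM (0.165), only the groups compared (0.0501), protein-coding genes only (0.115) and the covariate (0.0659). The extracellular matrix and adhesion call ended with protein-coding genes only (0.0572), and that of cytosolic ribosomal proteins by fry (0.171). Called anew without a low-count filter were Golgi structure (0.00315), OXPHOS (0.00341), glycosphingolipid synthesis (0.00679), nucleotide sugar supply (0.0205) and clathrin, caveolin and macropinocytosis genes (0.0443), higher, and RNase H and ASO-binding nuclear proteins (0.0363), lower. With the covariate they were the last list (0.0151, lower) and Golgi structure (0.0338, higher).

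**Figure D3:**
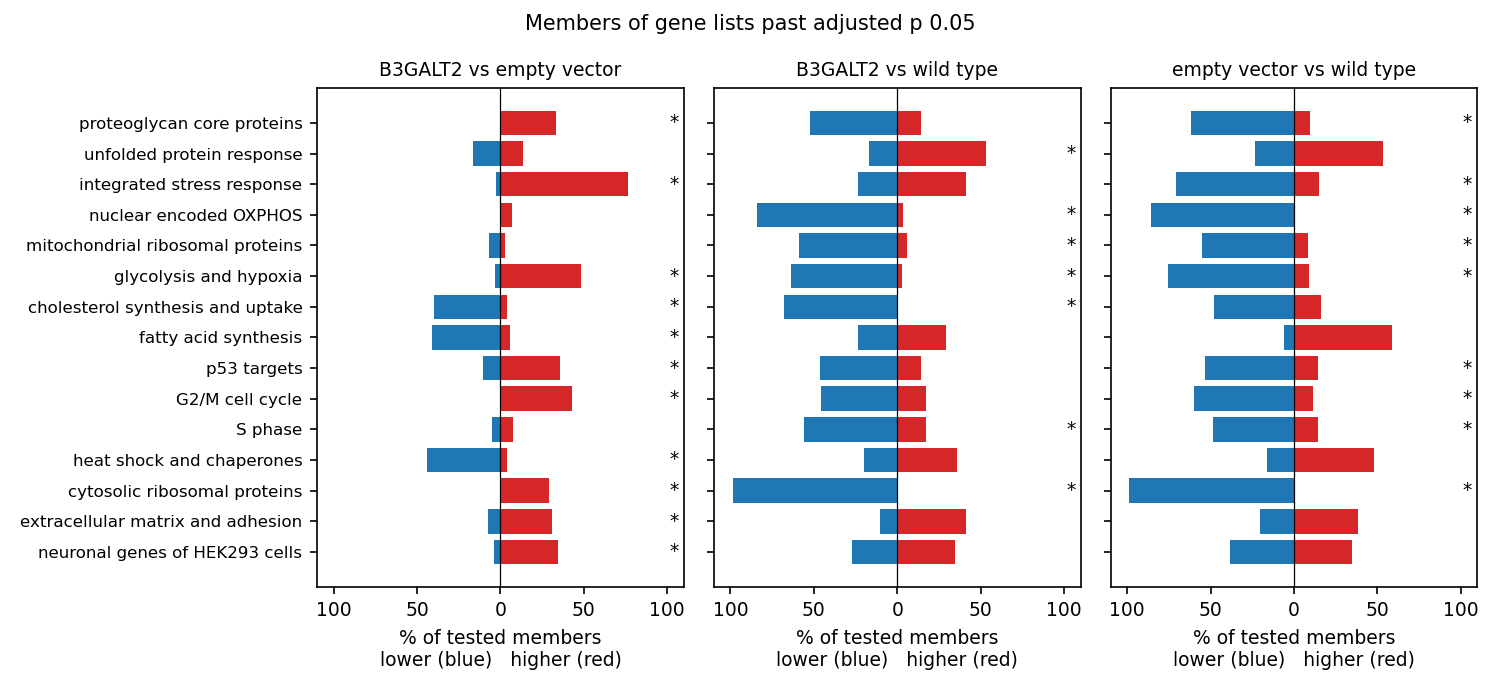
Share of tested members, in percent, that rose (right) or fell (left) at adjusted p under 0.05 in each of the 15 gene lists called in any comparison, one panel per comparison, with an asterisk where camera with a preset correlation gave adjusted p under 0.05. With B3GALT2 against empty vector 26 of 34 integrated stress response genes rose, and with empty vector against wild type 24 of 34 fell.

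The comparison of empty vector with wild type shows what the vector line differs in without B3GALT2. Cytosolic ribosomal protein genes were lower in empty vector, where of 75 members 0 rose, 74 fell and 1 did not pass (0 and 74 adjusted over the list alone), with a median of -0.75 and RPL13A (-1.17 ± 0.10) and RPS18 (-1.11 ± 0.11) as examples. These genes took 6.97, 7.17 and 7.21% of counts in empty vector replicates 1 to 3 and 11.04, 10.75 and 13.26% in wild type. Of 34 integrated stress response genes 5 rose, 24 fell and 5 did not pass (5 and 25 adjusted over the list alone), with DDIT4 (-1.43 ± 0.11) and ASNS, asparagine synthetase (-1.16 ± 0.18), falling. Among genes that qualified for naming, the largest rises were in the lncRNAs KCNQ1OT1 (3.20 ± 0.21) and XIST (2.38 ± 0.20) and in EGR1, an immediate early transcription factor (2.63 ± 0.12), FAM95C (2.57 ± 0.16), LY6G5B (2.46 ± 0.13) and YJEFN3 (2.45 ± 0.15). Large falls were in SDHAF4 (-2.02 ± 0.09), MVP (-1.92 ± 0.10), CRYL1 (-1.92 ± 0.13) and HAPLN2 (-1.80 ± 0.16) and the redox regulator TXNIP (-1.73 ± 0.06). MVP overlaps the more highly counted PAGR1. With the covariate, which is confounded with wild type, calls of named genes ended, among them KCNQ1OT1 (2.84, adjusted p = 0.106, edgeR) and ASNS (-0.61, adjusted p = 0.18).

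Energy metabolism lists were lower in empty vector than in wild type. Of 57 nuclear encoded OXPHOS genes, the respiratory chain and ATP synthase, 0 rose, 49 fell and 8 did not pass (0 and 49 adjusted over the list alone), with NDUFA13 (-0.81 ± 0.11) and COX7A2 (-0.78 ± 0.09) falling. Of 33 glycolysis and hypoxia genes 3 rose, 25 fell and 5 did not pass (5 and 25 adjusted over the list alone), with EGLN3 (-1.05 ± 0.11) and P4HA1 (-1.04 ± 0.07), both oxygen-dependent hydroxylases, falling. Of 71 mitochondrial ribosomal proteins 6 rose, 39 fell and 26 did not pass (6 and 37 adjusted over the list alone), with a median of -0.19 that was 0.10 on the TPM scale and 0.07 once trends with transcript length and GC were removed. MRPS34 (-0.70 ± 0.08) and MRPL43 (-0.70 ± 0.09) fell, and MRPL1 rose (0.72 ± 0.07).

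Cell cycle and surface lists moved the same way. Of 35 G2/M genes 4 rose, 21 fell and 10 did not pass (4 and 21 adjusted over the list alone), with a median of -0.26 that was 0.02 on the TPM scale. KIF2C (-0.78 ± 0.05) and CDK1, the mitotic kinase (-0.71 ± 0.04), fell, and the proliferation marker MKI67 (1.0 ± 0.09) and CENPF (0.86 ± 0.09) rose. The calls of MKI67 and CENPF ended with the covariate (adjusted p = 0.0839 and 0.0506, edgeR). Of 41 S phase genes 6 rose, 20 fell and 15 did not pass (6 and 20 adjusted over the list alone), with a median of -0.13 that was 0.15 on the TPM scale. Of 21 proteoglycan core proteins 2 rose, 13 fell and 6 did not pass (2 and 13 adjusted over the list alone), with GPC3 (-0.97 ± 0.06) and CD44 (-0.72 ± 0.07) falling. Of 28 p53 targets 4 rose, 15 fell and 9 did not pass (4 and 15 adjusted over the list alone), with a median of -0.26 that was 0.03 on the TPM scale and with PMAIP1 (-1.08 ± 0.05) and DDB2 (-0.84 ± 0.07) falling.

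By camera, adjusted p was 1.3e-25 for cytosolic ribosomal proteins, 2.4e-09 for OXPHOS, 4.1e-06 for glycolysis, 2.4e-04 for the integrated stress response, 0.00116 for G2/M, 0.00230 for mitochondrial ribosomal proteins, 0.010 for proteoglycans, 0.0158 for p53 targets and 0.0295 for S phase. In the same order, adjusted p was 0.494, 0.581, 0.494, 0.501, 0.177, 0.634, 0.494, 0.494 and 0.494 with an estimated correlation, so no call held there. In all, 10985 genes changed by edgeR, 5709 higher and 5276 lower, and 1936 changed at least 2-fold, 1425 higher and 511 lower. The 1936 were 412 with a filter at a mean of 5 CPM, 869 on the TPM scale, 947 with protein-coding genes only and 649 with the covariate, where 5315 genes changed in all. On the TPM scale 79.9% of calls were higher against 52.0% here, and the median of all genes moved from 0.01 to 0.22, so list changes there are relative to that shift. The S phase call ended with library totals as the only scaling (adjusted p = 0.0552), a filter at a mean of 5 CPM (0.0806), protein-coding genes only (0.0654) and the covariate (0.0835). That of p53 targets ended with the same filter (0.058) and the covariate (0.0604), that of nuclear encoded OXPHOS with the covariate (0.732), and that of mitochondrial ribosomal proteins by fry (0.0649). Lists called anew without a low-count filter were lower for cholesterol genes (0.00533), immediate early genes (0.0443), nucleotide sugar supply and sialyl- and fucosyltransferases (both 0.0491). Higher there were the unfolded protein response (0.0183), heat shock and chaperones (0.0254) and RNase H and ASO-binding nuclear proteins (0.044). With the covariate these 3 (8.2e-05, 3.2e-05 and 0.0354), fatty acid synthesis (0.0193) and lysosomal genes (0.0326) were called higher.

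The comparison of B3GALT2 with wild type measures the vector, its induction, B3GALT2 and other differences between the lines together. Cytosolic ribosomal protein genes were again lower in the vector line, where of 75 members 0 rose, 74 fell and 1 did not pass (0 and 74 adjusted over the list alone), with a median of -0.58 and RPS18 (-0.89 ± 0.11) and RPL13A (-0.85 ± 0.10) as examples. These genes took 8.01, 8.23 and 7.98% of counts in B3GALT2 replicates 1 to 3, against 11.04, 10.75 and 13.26% in wild type. Of 25 cholesterol synthesis and uptake genes 0 rose, 17 fell and 8 did not pass (1 and 18 adjusted over the list alone), with INSIG1, which holds sterol sensing in the endoplasmic reticulum (-1.15 ± 0.05), and the sterol oxidase MSMO1 (-0.91 ± 0.05) falling. Of genes that qualified for naming, the largest rises beside B3GALT2 were in KCNQ1OT1 (1.90 ± 0.24) and EGR1 (1.86 ± 0.13), the pseudogene LRRC37A8P (1.62 ± 0.13), and in BEX1 (1.58 ± 0.10) and the presynaptic gene PCLO (1.56 ± 0.11), both expressed in neurons. Large falls beside MSR1 were in the galectin ligand LGALS3BP (-1.60 ± 0.10), the polyamine enzyme SAT1 (-1.37 ± 0.09), the lipoprotein gene APOE (-1.32 ± 0.12) and the lncRNA MHENCR (-1.29 ± 0.09). The call of KCNQ1OT1 ended with the covariate (1.59, adjusted p = 0.372, edgeR).

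Of 57 OXPHOS genes 2 rose, 48 fell and 7 did not pass (2 and 50 adjusted over the list alone), with NDUFA13 (-0.66 ± 0.11) and COX7A2 (-0.66 ± 0.09) falling. Of 33 glycolysis and hypoxia genes 1 rose, 21 fell and 11 did not pass (2 and 21 adjusted over the list alone), with EGLN3 (-0.93 ± 0.11) and P4HA1 (-0.64 ± 0.07) falling and the hexokinase HK2 rising (0.35 ± 0.09), a call that ended without wild type replicate 3 (0.287, adjusted p = 0.146, edgeR) and with trends with length and GC removed (0.053, adjusted p = 0.705). Of 71 mitochondrial ribosomal proteins 4 rose, 42 fell and 25 did not pass (5 and 45 adjusted over the list alone), with a median of -0.21 that was 0.04 on the TPM scale and 0.01 once trends with length and GC were removed. Of 41 S phase genes 7 rose, 23 fell and 11 did not pass (7 and 23 adjusted over the list alone), with a median of -0.14 that was 0.10 on the TPM scale. E2F1 (-0.49 ± 0.06) and the licensing factor CDT1 (-0.42 ± 0.07) fell, and CLSPN (0.81 ± 0.07) and POLA1 (0.58 ± 0.07) rose. Of 30 unfolded protein response genes 16 rose, 5 fell and 9 did not pass (16 and 6 adjusted over the list alone), with the chaperone HYOU1 (0.53 ± 0.04) and SYVN1 (0.56 ± 0.08), a ubiquitin ligase of the endoplasmic reticulum, rising and CRELD1 (-0.60 ± 0.08) and DNAJB9 (-0.40 ± 0.09) falling. The DNAJB9 call ended on the TPM scale (-0.15, adjusted p = 0.134, limma) and with the covariate (-0.151, adjusted p = 0.541, edgeR). RNASEH1 (0.27 ± 0.07) and GCC2 (0.48 ± 0.09) rose, and M6PR (-0.08 ± 0.05) and ANXA2 (-0.08 ± 0.06) did not pass. The integrated stress response was not called here (14 higher, 8 lower, adjusted p = 0.504), but with the covariate it was called higher (4.0e-05). The difference between its changes against the 2 controls is the comparison of empty vector with wild type.

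By camera, adjusted p was 1.3e-27 for cytosolic ribosomal proteins, 5.3e-11 for OXPHOS, 1.5e-06 for cholesterol genes, 3.2e-05 for mitochondrial ribosomal proteins, 2.7e-04 for glycolysis, 0.0246 for S phase and 0.0484 for the unfolded protein response. In the same order, adjusted p was 0.523, 0.615, 0.523, 0.712, 0.615, 0.523 and 0.523 with an estimated correlation, so no call held there. In all, 8791 genes changed by edgeR, 4439 higher and 4352 lower, and 712 changed at least 2-fold, 506 higher and 206 lower. The 712 were 112 with a filter at a mean of 5 CPM, 194 on the TPM scale, 374 with protein-coding genes only and 171 with the covariate (83 higher and 88 lower), where 2541 genes changed in all. On the TPM scale 84.1% of calls were higher against 50.5% here, with the median of all genes at 0.17 against 0.00. The unfolded protein response call ended in each run that left out a library except B3GALT2 replicate 3 and wild type replicate 3 (adjusted p from 0.0604 to 0.127), and with RLE scaling (0.0518), a filter at a mean of 5 CPM (0.0622), only the groups compared (0.0768) and protein-coding genes only (0.0764). With the covariate the nuclear encoded OXPHOS call ended (0.888). Lists called anew without a low-count filter were p53 targets (0.0204), sialyl- and fucosyltransferases (0.0468) and G2/M (0.0484), lower, and extracellular matrix (0.0204) and ASO trafficking factors (0.0439), higher. With the covariate they were G2/M (0.00161) and sialyl- and fucosyltransferases (0.0496), lower. Higher there were lysosomal genes (0.00215), ASO trafficking factors (0.0287) and heat shock and chaperones (0.0316), beside the integrated stress response.

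Genes changed the same way against both controls set the B3GALT2 line apart from wild type and from the empty vector line, whatever the reason. There were 670 such genes by edgeR, 359 higher and 311 lower, and 30 of them changed at least 2-fold against each control, 10 higher and 20 lower. The 30 were 4 with a filter at a mean of 5 CPM, 4 on the TPM scale and 15 with the covariate. At a mean of 5 CPM or more, and ranked by the smaller of the 2 changes, the largest rises beside B3GALT2 were in CHAC1, TNC and SORCS1, in SLC16A7, a monocarboxylate transporter (0.70 ± 0.11 against empty vector and 1.06 ± 0.12 against wild type), SLC7A11 (0.67 ± 0.13 and 1.21 ± 0.13) and the glycine transporter SLC6A9 (0.87 ± 0.11 and 0.53 ± 0.11), which overlaps CCDC24. Next came the metalloprotease ADAMTS9 (0.48 ± 0.08 and 0.52 ± 0.08), the nuclear receptor ESRRG (0.47 ± 0.08 and 0.57 ± 0.08) and NHS (0.47 ± 0.11 and 0.88 ± 0.12). Against wild type CHAC1 was at 1.12 ± 0.16, TNC at 0.87 ± 0.12 and SORCS1 at 0.71 ± 0.10.

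At a mean of 5 CPM or more, the largest falls against both controls were in MSR1 and in 4 zinc-finger genes of chromosome 19, a class of DNA-binding proteins, namely ZNF875 (-1.04 ± 0.09 against empty vector and -1.14 ± 0.09 against wild type), ZNF264 (-0.98 ± 0.11 and -0.90 ± 0.12), ZNF569 (-0.81 ± 0.11 and -1.0 ± 0.12), which overlaps ZNF570, and ZNF134 (-0.92 ± 0.09 and -0.63 ± 0.10). The lncRNA FOXCUT (-0.70 ± 0.08 and -0.58 ± 0.08), C1QTNF6 (-0.56 ± 0.09 and -0.91 ± 0.09), the fatty acid carrier FABP5 (-0.58 ± 0.07 and -0.54 ± 0.07), the death receptor TNFRSF10A (-0.60 ± 0.10 and -0.53 ± 0.11) and GGT1 (-0.64 ± 0.11 and -0.51 ± 0.11), which overlaps the more highly counted LRRC75B, fell too. Zinc-finger and GGT1 reads can be shared with close paralogs. Against wild type the call of ESRRG ended with trends with length and GC removed (0.174, adjusted p = 0.0808, edgeR), and those of GGT1 (0.0904) and TNFRSF10A (0.107) on the TPM scale (limma). With the covariate, which is confounded with wild type, the edgeR calls against wild type of TNC, SORCS1, SLC16A7, SLC7A11, SLC6A9, ADAMTS9, ESRRG, NHS, FABP5 and GGT1 ended (adjusted p from 0.0688 to 0.288).

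Both comparisons use the same B3GALT2 libraries. Simulated unchanged groups gave 0 genes called the same way, and independent lists of the same sizes would share 567.3 higher and 657.1 lower genes, so the observed 359 and 311 lay below independent overlap. At 2-fold, 10 and 20 genes were observed where independent lists would share 1.51 and 6.40. Another 1965 genes changed in opposite directions against the 2 controls. The covariance of the fold changes was -0.06 against 0.01 simulated, and the correlation across genes -0.305 against 0.484. Fold changes against empty vector and those of empty vector against wild type had a correlation of -0.750 against -0.444 simulated, and a covariance of -0.21 against -0.01. In those comparisons 3808 genes changed in opposite directions and 130 in the same direction, where independent lists would give 1536 opposite. Groups of 3 libraries cannot be halved with 2 in each, so the shared libraries stay part of these relations. For fold changes against empty vector and those of empty vector against wild type, noise between replicates gave a small part of the covariance (-0.01 simulated, -0.21 observed). A difference common to the 3 empty vector libraries would also enter both with opposite signs. The simulation held none, so the whole part due to the shared libraries is not known. The count of 670 was 349 and 358 without B3GALT2 replicates 1 and 2, 392 and 399 without empty vector replicates 1 and 2, and 1288 without wild type replicate 3.

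**Figure D4:**
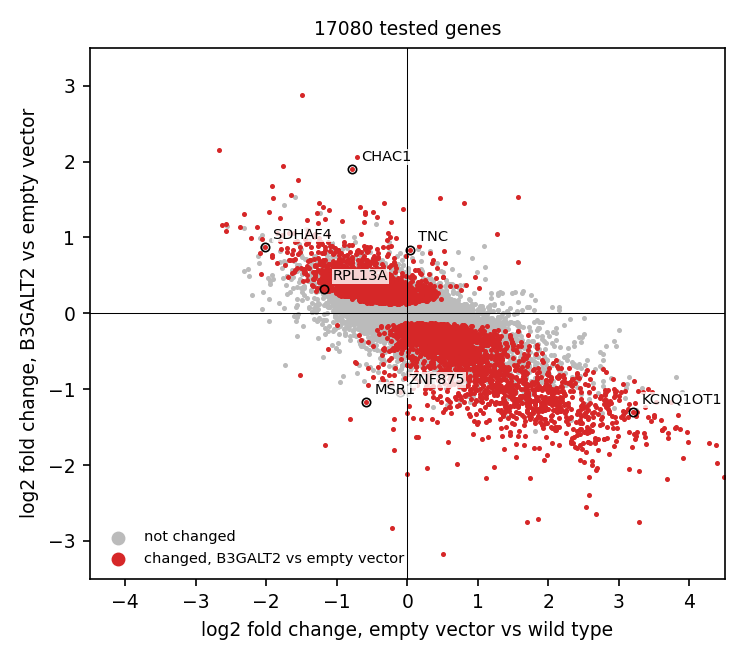
Log2 fold change of B3GALT2 against empty vector (vertical) and of empty vector against wild type (horizontal) for tested genes, 17070 drawn and 10 outside the axes, B3GALT2 among them. Both axes use the empty vector libraries. Simulated unchanged groups gave a correlation across genes of -0.444 and a covariance of -0.01, against -0.750 and -0.21 observed.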

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

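Chosen only after seeing the data were the runs with protein-coding genes only, with length and GC trends removed, and with a covariate for variation within groups. Of 320 pairs of a named gene and a comparison in which it passed, 192 kept their call and direction in every alternative run. Of 6363 values 6067 kept them, 277 kept their sign but no longer passed, and 19 changed sign. Runs that left out 1 library ended calls of named genes against empty vector, namely those of B3GALT1, B3GALT6, BAX, C1GALT1C1, CERS4, GOLGA3, GPI, INSIG1, ITGB3, LRP2, MOGS, MRPL1, RPL13A, ST3GAL5, ST8SIA2 and SYVN1. On the log2(TPM + 1) scale 43 calls ended by limma with the sign kept, apart from the changes of sign given below. Beyond the genes just named these included RAB27A (adjusted p = 0.177), STARD4 (0.126), HSF2 (0.0945), CREB3L1 (0.0776), NHS (0.063) and ELOVL6 (0.0509) against empty vector. With only the groups compared the call of PDK1 ended (0.0584, edgeR). Without a low-count filter 8 calls ended. The covariate ended 78 of the 277 calls that kept their sign. Its score was 0.474 to 2.185 in wild type and -0.758 to -0.451 in the vector lines, so it is confounded with the comparisons with wild type. The alternative without mitochondrially encoded genes was not run, since the table holds 0 of them. Depth limits genes near 1 CPM, and STAB1 and STAB2 had too few reads to test. Where a cause is not named below, the cause was not tested.

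With a filter at a mean of 5 CPM or more the genes changed at least 2-fold numbered 42 for B3GALT2 against empty vector, 112 for B3GALT2 against wild type, 412 for empty vector against wild type and 4 against both controls, and with protein-coding genes only 224, 374 and 947 in the first 3. On the log2(TPM + 1) scale they numbered 106, 194, 869 and 4, and 324 genes changed the same way against both controls. With only the groups compared in the fit, 7888 genes changed against empty vector and 1227 against both controls. With the covariate, 7580 genes changed against empty vector, 2541 between B3GALT2 and wild type (171 at least 2-fold), 5315 between empty vector and wild type (649), and 333 against both controls (15), and 12 lists were called between B3GALT2 and wild type. Without a low-count filter 17, 12 and 16 lists were called in the 3 comparisons, with an estimated correlation 1, 0 and 0, and by fry 21, 27 and 27. Lists not called against empty vector were called in some runs beyond those in the report: RNase H and ASO-binding nuclear proteins lower with library totals (adjusted p = 0.0498), a filter at a mean of 5 CPM (0.0177), only the groups compared (0.0158), protein-coding genes only (0.0232), and without wild type replicate 3 (0.0109) or empty vector replicate 2 (0.0241), glycosphingolipid synthesis higher without B3GALT2 replicate 2 (0.0459) or empty vector replicate 1 (0.0443), and nuclear encoded OXPHOS higher without wild type replicate 3 (0.0176) or with only the groups compared (0.00945), where Golgi structure and retrograde transport was called too (0.0466). Without wild type replicate 3, G2/M genes were called lower between B3GALT2 and wild type (0.0484), and in empty vector against wild type the unfolded protein response (0.0112), heat shock and chaperones (0.0147), RNase H and ASO-binding nuclear proteins (0.0307) and fatty acid synthesis (0.0418) were called higher. Cholesterol synthesis and uptake was called lower there without wild type replicate 2 (0.042) or empty vector replicate 3 (0.0207). Leaving out 1 library gave 3008 to 7560 genes against empty vector, 349 to 1288 against both controls, and a log2 fold change of B3GALT2 between empty vector and wild type of -0.13 (without wild type replicate 1) to 1.77, from 9 reads in empty vector and 4 in wild type.

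Named genes that changed sign did so in comparisons with wild type. With the covariate these were, for empty vector, ATF3 (0.116), CDC73 (-0.007), ELOVL6 (-0.023), GCC2 (-0.080), RNASEH1 (-0.048), SESN2 (0.092), SLC16A7 (-0.214) and STMN3 (0.077), and for B3GALT2, CERS4 (0.155), NDUFA13 (0.014) and RNASEH1 (-0.058). On the TPM scale they were, for empty vector, ATF3 (0.054), NDC80 (0 as rounded), SESN2 (0.050) and STMN3 (0.043), and for B3GALT2, HSF2 (0.022), RAB11A (0.085) and SCD5 (0.051). The median of all genes on that scale was 0.22 for empty vector and 0.17 for B3GALT2. All of these genes lay below it, so they were still low relative to other genes. With length and GC trends removed LRP2 was at -0.134 for empty vector.

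Replicate numbers do not pair the samples: libraries with the same number had correlations of -0.108 to 0.108 in their deviations from group means. With the replicate block 4453, 8471 and 10803 genes changed in the 3 comparisons, 584, 709 and 1942 of them at least 2-fold, with 594 against both controls (27 at least 2-fold) and 11, 6 and 9 lists called. The calls of C1GALT1C1 (adjusted p = 0.0541), INSIG1 (0.0511) and ST3GAL5 (0.0515) against empty vector ended by edgeR, and so did the list call of the unfolded protein response between B3GALT2 and wild type (0.0593, camera). Not every library correlated best with its own number.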

Other observations

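Some tests were chosen only after the result was seen. These were of genomic DNA by genes with no read in wild type, and of overlapping genes by silent genes nested in expressed genes. The others were of the spread over chromosomes, of a gain of chromosome 18, and of the deviation of wild type replicate 3. Gene lists not yet described gave no call by camera between B3GALT2 and empty vector. Among them fry called Golgi structure and retrograde transport (adjusted p = 0.0239), clathrin, caveolin and macropinocytosis (0.0459) and kidney epithelial markers (0.0239) higher. Of 46 Golgi structure and retrograde transport genes 8 rose, 3 fell and 35 did not pass (6 and 2 adjusted over the list alone, adjusted p = 0.105), with CREB3L1 (0.42 ± 0.11) rising and the golgin GOLGA3 (-0.22 ± 0.07) falling. Of 42 lysosomal genes 6 rose, 10 fell and 26 did not pass (7 and 11 adjusted over the list alone, adjusted p = 0.925), with the proteases CTSB (0.35 ± 0.06) rising and CTSA (-0.34 ± 0.05) falling. Of 30 unfolded protein response genes 4 rose, 5 fell and 21 did not pass (4 and 5 adjusted over the list alone, adjusted p = 0.533). Its sensor ERN1 rose (0.43 ± 0.07), and the chaperone HSPA5 fell (-0.31 ± 0.05). Of 32 genes of clathrin, caveolin and macropinocytosis 8 rose, 4 fell and 20 did not pass (8 and 4 adjusted over the list alone, adjusted p = 0.269), with CAVIN1 (0.31 ± 0.05) rising. Of 28 immediate early genes 7 rose, 2 fell and 19 did not pass (7 and 2 adjusted over the list alone, adjusted p = 0.287), with ATF3 (0.51 ± 0.08) and JUN (0.37 ± 0.06) rising and EGR1 (-0.77 ± 0.09) falling.

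Other lists were not called in this comparison either. For OXPHOS 4 of 57 rose and 0 fell, for mitochondrial ribosomal proteins 2 of 71 rose and 5 fell, for S phase 3 of 41 rose and 2 fell, for interferon-stimulated genes 2 of 30 rose and 3 fell, and for replication-dependent histones 1 of 28 rose and 3 fell, with adjusted p = 0.144, 0.824, 0.642, 0.60 and 0.365. For NF-kappaB and cytokines 2 of 13 rose and 1 fell, and for cadherins 4 of 21 rose and 4 fell (adjusted p = 0.925 and 0.830). Kidney epithelial markers had CUBN higher (1.04 ± 0.17) and LRP2 lower (-0.17 ± 0.06), with adjusted p = 0.533 for the list. Of other cell types, fibroblast markers had 2 of 9 higher and 2 lower, MMP2 (0.51 ± 0.11) and COL3A1 (-1.22 ± 0.20) among them, and hepatocyte and keratinocyte markers had 0 of 5 and 0 of 6 either way at adjusted p = 0.529, 0.718 and 0.925 by camera.

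Of the 1936 genes changed at least 2-fold between the controls, 1810 (93.5%) had the B3GALT2 mean between them. The median position was 0.559 from wild type (0) to empty vector (1). These genes were chosen for a wide gap between the controls, which favours a mean between them, and no share expected from that choice was computed. After trends with transcript length and GC were removed 1630 of the 1936 calls stayed, although the changes followed length across genes (Spearman rho 0.328). Both values were known for 14687 of 17080 tested genes, and the others were not corrected. The 1630 may include uncorrected genes, whose number was not counted, so the test does not decide on this bias. Genomic DNA in the empty vector libraries would add equally per unit length. A background was taken from 2714 genes with no read in wild type and no expressed gene nearby, which gained 0.0155 CPM per gene. Per unit length 99.2% of the 2-fold higher genes gained more than 3 times that, and 99.9% by silent genes as first defined. Selection raised both shares, since called genes passed the low-count filter and silent genes as first defined were capped at a mean of 0.1 CPM. The shares therefore do not exclude genomic DNA for the 2-fold higher genes. Reads from unspliced RNA of overlapping genes could not account for all of them, since 45.9% (650 of 1417) overlapped another gene with more counts, against 15.3% of other tested genes. For those that overlap they may contribute: silent genes nested in expressed genes gave 2.70 times the wild type signal in empty vector and 1.53 times in B3GALT2, against 1.36 and 1.06 for silent genes away from expressed ones, while a difference between the lines or of B3GALT2 itself was not tested.

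Genes changed the same way against both controls were unevenly spread over chromosomes, with 26 of 261 genes of chromosome 18 higher and 0 lower (adjusted p = 2.5e-09, Fisher's exact test), and 49 of 1096 of chromosome 19 and 21 of 441 of chromosome 22 lower (1.3e-07 and 9.8e-04), and with few higher on chromosomes 8, 19 and 22 (3, 9 and 1 genes, adjusted p = 0.016, 0.0115 and 0.016). Intervals of medians below are bootstraps over genes, so they measure the spread among genes and leave out that between libraries or lines. A gain of the whole of chromosome 18 in the B3GALT2 line cannot be told apart. Both arms were higher against both controls as tested, with the lowest median 0.097 (95% interval 0.011 to 0.185) for the short arm against wild type. That median was 0.061 (-0.018 to 0.175) with length and GC trends removed. Whole-chromosome medians were small, 0.126 (0.098 to 0.154) against empty vector and 0.163 (0.113 to 0.239) against wild type. The test asked whether medians exceeded 0, and not whether their size suits a gain in all cells. Bias in length and GC cannot be told apart either, because a bound of 0.05 was passed by the corrected median of the whole chromosome against empty vector (0.10, 0.07 to 0.13) and lay within the interval against wild type (0.087, 0.027 to 0.126). Loss of a chromosome 19 segment, which would need a median under -0.3 against both controls, was argued against by the 29 neighbours of the named zinc-finger genes in the comparison with empty vector (-0.10, -0.248 to 0.084), while that with wild type (-0.175, -0.394 to 0.036) did not exclude it, so it cannot be told apart. No biological explanation of the spread was tested.

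MSR1 was lower in B3GALT2 than in both controls. Loss of a chromosome 8 segment of 5 Mb on either side was argued against by its 42 tested genes. Their median log2 change was -0.047 (bootstrap interval over genes -0.096 to 0.012) against empty vector and -0.068 (-0.181 to 0.079) against wild type. The nearest tested genes on each side, TUSC3 (0.03 and -0.35) and MICU3 (0.02 and -0.13), did not fall against empty vector, and the lowest, LINC02905 (-1.19 and 0.72, mean level 0.51 CPM), is farther off, so a segment between the nearest 2 stays open. GripTite is, as background, a trade name of a HEK293 derivative engineered to express MSR1, and whether a construct carried by these cells was silenced or lost stays open and was not tested. An effect of B3GALT2 on MSR1 was not tested apart from the line and stays open.

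Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The counts of genes were 4762, 8791 and 10985, and of genes changed at least 2-fold 582, 712 and 1936, against a highest other split of 0 in each case. For gene lists the real and the highest other were 11 and 10 for B3GALT2 against empty vector, 7 and 6 for B3GALT2 against wild type, and 9 and 9 for empty vector against wild type, where 3 of 10 splits gave as many. For genes changed the same way against both controls, 3 of 100 splits of the 9 libraries gave 670 or more, the real one included. The highest other was 7469, and for 2-fold changes 741 against 30, from splits that set the wild type libraries apart against mixed vector groups, which points to the structure of the samples. The 95 splits that set apart libraries of more than one group gave 0, and pooling groups that differ would bring that about, so the share measures the structure of the groups and says little on chance. Across 11645 genes, the change of B3GALT2 against empty vector had a Spearman rho of 0.073 with the deviation of wild type replicate 3 from replicates 1 and 2. Of the genes called at 5 CPM or more, 1870 of 3484 went the same way as that deviation, and 29 of the 37 that changed at least 2-fold did.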
